A study of Mus musculus with 14 samples.

How the data were processed

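Poly(A) RNA from sorted OT-I CD8+ T cells was sequenced as stranded libraries, 14 in all: 3 each for Naive, OVA, ERY1-OVA and TER119-SIINFEKL and 2 for SIINFEKL. The authors deposited normalized values as log2 RPKM (reads per kilobase of gene, scaled to the reads of the library). The authors' processing notes name bcl2fastq 2.17.1.14, STAR 2.4.2, edgeR and the builds GRCm38 and mm10. They state no order or role for these, and no counter, annotation, gene lengths, filter, prior count or normalization between libraries. Counts were not used here, so the depth per library is unknown and no counting interval was given. The log base was read from the values, of which 4.3% were negative. Read as base 2, RPKM multiplied by exon length in kilobases summed to 1764368 to 2042896 per library, and read as base e to 22638320 to 37606456; the unit implies the order of the former.

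The test had been set before the data were examined, on the assumption of RPKM to which 1 would be added before the logarithm. Because the values were already logarithms, they were used as deposited, which was the fallback set beforehand. Genes with a mean RPKM of at least 1 were kept, which left 9793 genes and removed 313. Limma 3.58.1 in R 4.3.3 was fitted to 5 group means with a mean-variance trend (9 residual and 4.6 prior degrees of freedom). Tests were two-sided, and Benjamini-Hochberg adjusted p under 0.05 within a comparison was called. Replicate number was not used as a term. The 10 comparisons were each antigen group against Naive, ERY1-OVA against OVA, TER119-SIINFEKL against SIINFEKL, the targeted groups against each other, the soluble groups against each other, targeted against soluble antigen, and the difference of the targeting effect between protein and peptide.

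Gene lists were fixed before the data were examined, 18 in all: G2/M and mitosis, S phase and DNA replication, inhibitory receptors, anergy and T cell receptor attenuation, cytotoxic effectors, cytokines and chemokines, effector transcription factors, naive and memory genes, activation surface markers, trafficking receptors, immediate-early and handling stress genes, type I interferon response, pro-apoptotic genes, glycolysis, oxidative phosphorylation, cholesterol biosynthesis, regulatory T cell genes and cytosolic ribosomal proteins. Camera from limma tested each list against all other genes with a preset correlation of 0.01, and again with an estimated correlation, adjusted over the 18 lists of a comparison. Fry, also from limma, tested whether members moved on balance in one direction. Markers of other cell types were fixed in the same way.

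Named genes followed a rule fixed with the design. It took the 5 largest rises and the 5 largest falls among called genes whose group values did not overlap, up to 4 members per list with the smallest adjusted p, and a core set of T cell genes. Positions come from the GENCODE annotation of GRCm38, matched by Ensembl gene identifier for 10039 genes, while 67 had no match. For comparisons that share the Naive libraries, 50 simulations of unchanged groups gave the values that sharing alone produces.

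Alternatives were quantile normalization, median-of-ratios rescaling, a pseudocount of 0.1, no filter, a filter at a mean RPKM of 3, no trend, robust moderation, array weights, a replicate block, a fit of only the groups compared, a 2-fold requirement and leaving out each library. Added after seeing the data were a pseudocount of 1, a correction per library for gene length and GC content (9716 genes), leaving out OVA replicate 1 with TER119-SIINFEKL replicate 1, and leaving the SIINFEKL group out of the fit. Where 1 SIINFEKL library was left, it was assumed to vary like the other groups.

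The procedure was tested on simulated data. Of genes changed by log2 0.5, 1 and 2 in 3 libraries, 31.3%, 83.6% and 98.5% were recovered, and 9 unchanged genes were called. A shifted list was called with no other list. The simulated genes varied independently, so this does not test list calls among genes that vary together. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.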

Results

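The series measured polyadenylated RNA in ovalbumin-specific CD8+ T cells recovered from mouse spleen. The cells were OT-I cells, which carry a transgenic T cell receptor for the ovalbumin peptide SIINFEKL, and they were transferred on day 0. On day 1 the recipients received 223 pmol of antigen by vein, and spleens were taken on day 4. Antigen was whole ovalbumin (OVA, 3 libraries), ovalbumin joined to the erythrocyte-binding peptide ERY1 (ERY1-OVA, 3 libraries), free SIINFEKL peptide (2 libraries), or the peptide joined to a TER119 antibody fragment that binds erythrocytes (TER119-SIINFEKL, 3 libraries). Mice that received saline, named Naive (3 libraries), gave the background level. Values were deposited as log2 RPKM for 14 libraries, and 9793 genes were tested. Read counts were not used here, so the depth behind each value is unknown. Fold changes are log2 values with their standard error (SE) from limma, and group levels are means with SD. Each gene named as having risen or fallen passed the test, and its values in the groups compared did not overlap. Counts of list members that rose or fell rest on the test alone, and values of a counted member may overlap.

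Transcripts of CD8+ T cells were abundant in every library. Cd8a lay between 246.92 and 398.53 RPKM and Cd3e between 301.32 and 431.15 RPKM, while Cd4 stayed between 0.18 and 1.31 RPKM. The log2 fold change of Cd8a from Naive was -0.46 ± 0.10 (SE, 3 against 3 libraries) after OVA and -0.45 ± 0.10 after TER119-SIINFEKL. Cd8b1, the other CD8 chain, was lower than Naive after TER119-SIINFEKL (-0.94 ± 0.11, adjusted p = 1.5e-05), ERY1-OVA (-0.56 ± 0.11) and OVA (-0.47 ± 0.11, and -0.80 with the length and GC correction). The other shifts of these identity genes from Naive were in Cd8a after ERY1-OVA (-0.33 ± 0.10, a call lost without Naive replicate 1 or 3 or ERY1-OVA replicate 3, at -0.33 to -0.29, and -0.51 with the length and GC correction) and Cd3e after OVA (-0.39 ± 0.09, and -0.59 with that correction).

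Markers fixed for other cells differed from Naive as well. The B cell gene Cd22 was higher after OVA (4.18 ± 0.14, SE, 3 against 3 libraries), SIINFEKL (3.33 ± 0.16, 2 against 3), ERY1-OVA (4.03 ± 0.14) and TER119-SIINFEKL (4.94 ± 0.14). The macrophage gene Cd68 was higher after TER119-SIINFEKL (1.26 ± 0.35) and ERY1-OVA (1.24 ± 0.35, but 1.01 without Naive replicate 2 and 0.85 without ERY1-OVA replicate 3, each with the call lost), with 0.88 ± 0.35 after OVA at the threshold (adjusted p = 0.05). That call was lost with the length and GC correction (0.55), and without Naive replicate 2 or 3, ERY1-OVA replicate 2 or any 1 library of OVA or TER119-SIINFEKL (0.65 to 1.00). Pecam1, fixed as an endothelial marker, was higher after SIINFEKL (0.92 ± 0.15) and ERY1-OVA (0.40 ± 0.14). The latter call was lost without Naive replicate 1 or 3 or any 1 ERY1-OVA library (0.35 to 0.43) and with quantile normalization (0.32). Pecam1 stood at 20.95 to 65.73 RPKM over all libraries. It was the 1 of 6 stromal and endothelial markers with values, so the cells it came from cannot be told. H2-Aa, of MHC class II, was lower after ERY1-OVA (-1.94 ± 0.66), a call lost without Naive replicate 1 or 3 or ERY1-OVA replicate 2 (-1.86 to -1.51). After OVA the dendritic cell gene Itgax was higher (0.84 ± 0.32), a call lost with quantile normalization, the length and GC correction, and without Naive replicate 2 or any 1 library of OVA, ERY1-OVA or TER119-SIINFEKL (0.38 to 0.92). The NK cell gene Klrb1c was lower there (-0.92 ± 0.33), a call lost when any 1 Naive library or OVA replicate 2 or 3 was left out (-0.97 to -0.68).

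OVA replicate 1 and TER119-SIINFEKL replicate 1 held more transcript of MHC class II genes, with Cd74 at 34.36 and 19.21 RPKM against 4.12 to 15.07 RPKM in the other libraries. The haemoglobin gene Hba-a1 reached 9.08 RPKM in TER119-SIINFEKL replicate 1 and 0.64 to 4.90 RPKM elsewhere. In both libraries, long genes read low relative to their group, with rank correlations across genes of -0.47 and -0.46 between deviation and gene length. The SIINFEKL pair differed from each other most. The SD within the group, as the square root of the mean variance over genes, was 0.416 against 0.226 to 0.255 in the other groups. Limma shared 1 spread per gene over all 5 groups. For genes that varied more in the SIINFEKL pair, SEs were thus too small in comparisons with SIINFEKL and too large in the others.

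The first principal component set the Naive libraries apart. It held 63.6% of the variance and placed Naive libraries between -61.3 and -55.9 and the OVA, ERY1-OVA and TER119-SIINFEKL libraries between 21.6 and 30.8. SIINFEKL replicate 1 lay at -11.9 and SIINFEKL replicate 2 at -48.3, next to the Naive libraries.

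**Figure D1:**
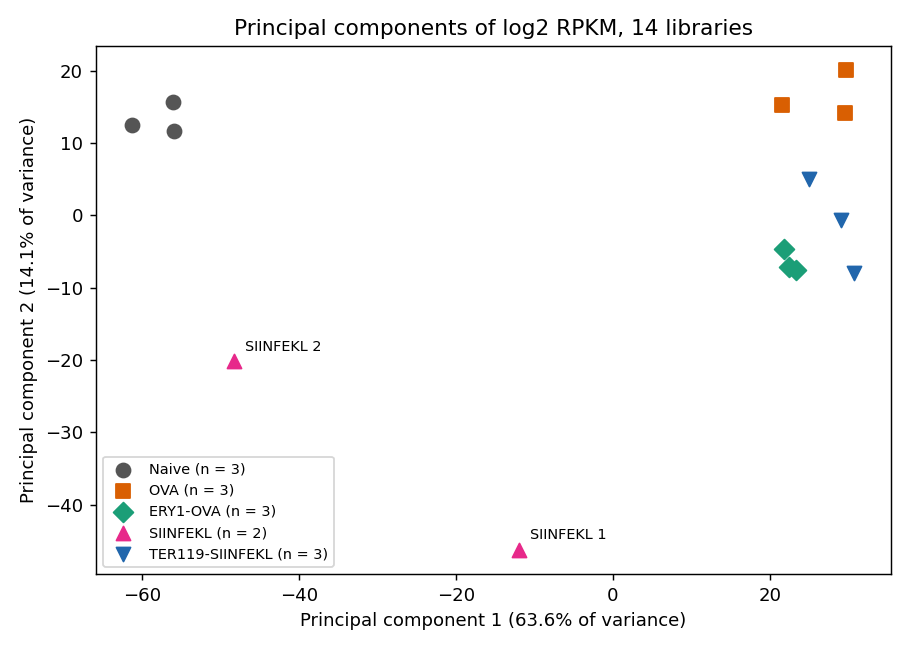
Each point is 1 library on the first and second principal components of log2 RPKM (axes in component scores, with the percent of variance), coloured by group. The 3 Naive libraries lie at -55.9 or below on the first component, the OVA, ERY1-OVA and TER119-SIINFEKL libraries at 21.6 or above, and the SIINFEKL pair at -11.9 and -48.3.

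OVA was compared with Naive to see how the cells responded to soluble protein. Cell division genes were higher: 22 of 22 measured G2/M and mitosis genes rose, by a median of 5.12, and 22 of 22 S phase and DNA replication genes rose, by a median of 2.87. Ccnb1, which encodes the mitotic cyclin B1, rose by 5.61 ± 0.33 (SE, 3 against 3 libraries), Mki67, a marker of cycling cells, by 5.03 ± 0.55, and Mcm5, part of the replicative helicase, by 2.94 ± 0.15. E2f8 (log2 fold change 6.37 ± 0.68), Tk1 (5.92 ± 0.46), Hmmr (5.82 ± 0.52), Kif15 (5.78 ± 0.56) and Kif2c (5.78 ± 0.48) had the largest rises. Of 10 inhibitory receptors, 7 rose, among them Lag3 (5.02 ± 0.63), Pdcd1, which encodes PD-1 (4.82 ± 0.59), and Ctla4 (3.54 ± 0.43). Most genes of the metabolic lists also rose: 10 of 15 glycolysis genes, such as Tpi1 (1.87 ± 0.13) and Gapdh (1.65 ± 0.11), 23 of 26 oxidative phosphorylation genes, such as Sdhb (0.98 ± 0.11), and 12 of 18 cholesterol biosynthesis genes, such as Idi1 (1.57 ± 0.18). Effector genes moved apart, since 6 cytotoxic effector genes rose and 3 fell of 17. Granzyme genes Gzmk (3.75 ± 0.38) and Gzmb (1.65 ± 0.40) rose, as did the transcription factors Irf4 (2.98 ± 0.26), Irf8 (2.68 ± 0.25) and Tbx21 (1.06 ± 0.22). Among 18 naive and memory T cell genes 13 fell and 1 rose; the fallen ones included the IL-7 receptor gene Il7r (-1.96 ± 0.21), the survival gene Bcl2 (-1.63 ± 0.18) and S1pr1, a receptor for egress from lymphoid organs (-1.16 ± 0.11). Nr1d1 (-2.14 ± 0.38), Igfbp4 (-2.03 ± 0.36), Fam211b (-2.02 ± 0.34) and Acvrl1 (-1.99 ± 0.54) had the largest falls beside Il7r. Type I interferon response genes fell in 7 of 19 cases, for example Ddx58, a sensor of viral RNA (-0.73 ± 0.14). The anergy and T cell receptor attenuation list moved apart, with 3 of 14 genes higher and 2 lower. Egr2, an anergy-associated transcription factor, had a fold change of -0.32 ± 0.14 (adjusted p = 0.076), and Ifng one of 1.77 ± 0.78 (adjusted p = 0.076).

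In OVA against Naive, limma called 4659 of 9793 genes, 2392 higher and 2267 lower. The higher share was 51.3% but 42.9% with quantile normalization and 42.1% with the length and GC correction, so the balance turned with scaling. The list test (camera) gave adjusted p = 4.5e-18 for G2/M, 7.5e-19 for S phase, 0.0045 for inhibitory receptors, 1.2e-05 for glycolysis, 1.9e-07 for oxidative phosphorylation, 0.00011 for cholesterol biosynthesis, 1.2e-05 for naive and memory genes and 0.014 for the interferon response. In the same order these were adjusted p = 0.2, 0.11, 0.24, 0.11, 0.29, 0.17, 0.17 and 0.69 with an estimated correlation. The anergy list (adjusted p = 0.92, median -0.05, mean 0.15) and the cytotoxic list (adjusted p = 0.84, median -0.15, mean 0.32) did not pass, and their medians and means differed in sign. Adjusted over the list alone, the counts stayed at those given, except in the anergy list, where 4 genes were higher and 3 lower. Without OVA replicate 2 the interferon list had adjusted p = 0.069, and with a requirement of a 2-fold change 1083 genes were called. Fold changes of genes low in 1 group depended on the unstated prior count of the values: with a pseudocount of 1 they were E2f8 3.89, Kif2c 3.78, Pdcd1 3.04, Nr1d1 -1.21 and Acvrl1 -1.22.

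ERY1-OVA was compared with Naive to see the response to erythrocyte-targeted protein. Lag3 had the largest rise, 6.29 ± 0.63 (SE, 3 against 3 libraries), from a log2 RPKM of -0.66 ± 0.35 (SD, n = 3) to 5.63 ± 0.26 (SD, n = 3), and 8 of 10 inhibitory receptors rose, Pdcd1 by 5.46 ± 0.59, Ctla4 by 4.80 ± 0.43 and Cd200 by 3.15 ± 0.42. All 22 G2/M genes rose, by a median of 5.03, and 21 of 22 S phase genes, by a median of 2.39; Mki67 rose by 5.19 ± 0.55 and Mcm5 by 2.42 ± 0.15. E2f8 (6.04 ± 0.68), Hmmr (5.82 ± 0.52), Kif4 (5.79 ± 0.50) and Kif2c (5.68 ± 0.48) were the other genes with the largest rises. Anergy and receptor attenuation genes rose in 6 of 14 cases and fell in 1. Folr4, which encodes folate receptor 4, rose by 3.44 ± 0.25, Ikzf2, which encodes the transcription factor Helios, by 2.33 ± 0.28, and Egr2 by 0.91 ± 0.14. Glycolysis genes rose in 8 of 15 cases (Gapdh by 1.22 ± 0.11), oxidative phosphorylation genes in 16 of 26 (Sdhb by 0.78 ± 0.11), and cholesterol biosynthesis genes in 8 of 18 with 1 lower (Cyp51 by 1.03 ± 0.12). Gzmb had a fold change of -0.10 ± 0.40 (adjusted p = 0.85) and Tbx21 of 0.43 ± 0.22 (adjusted p = 0.13), while Gzmk rose by 1.94 ± 0.38 and the perforin gene Prf1 had a fold change of -1.05 ± 0.20. Naive and memory genes fell in 11 of 18 cases and rose in 2. The largest falls were in Igfbp4 (-3.70 ± 0.36), Fam211b (-2.98 ± 0.34), the integrin gene Itgae (-2.79 ± 0.31), Il7r (-2.64 ± 0.21) and the chemokine receptor gene Ccr9 (-2.57 ± 0.44).

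In ERY1-OVA against Naive, 3905 genes were called, 2048 higher and 1857 lower (52.4% higher, but 43.5% with quantile normalization and 42.2% with the length and GC correction). Camera gave adjusted p = 8.7e-20 for G2/M, 6.4e-19 for S phase, 7.4e-05 for inhibitory receptors, 0.043 for anergy, 0.0087 for glycolysis, 1.4e-05 for oxidative phosphorylation, 0.014 for cholesterol biosynthesis and 0.00028 for naive and memory genes. In that order they were adjusted p = 0.27, 0.2, 0.21, 0.47, 0.27, 0.37, 0.37 and 0.27 with an estimated correlation. With p-values adjusted over the list alone, 9 inhibitory receptors, 21 oxidative phosphorylation genes and 10 cholesterol genes were higher, 13 naive and memory genes, 1 glycolysis gene and 2 cholesterol genes were lower, and the other counts of these lists did not change. The anergy list lost its call without ERY1-OVA replicate 1 (adjusted p = 0.14), Naive replicate 1 (0.068) or Naive replicate 3 (0.055), with the filter at a mean RPKM of 3 (0.056), with quantile normalization (0.06), array weights (0.075) or a pseudocount of 1 (0.052). With a 2-fold requirement 1009 genes were called. That pseudocount gave E2f8 3.58, Kif4 3.50, Kif2c 3.69, Pdcd1 3.63 and Gzmk 1.20, and 1.01 for the inhibitory receptor median.

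TER119-SIINFEKL was compared with Naive to see the response to erythrocyte-targeted peptide. 9 of 10 inhibitory receptors rose, by a median of 2.08: Lag3 by 6.72 ± 0.63 (SE, 3 against 3 libraries), Pdcd1 by 6.50 ± 0.59, Ctla4 by 4.82 ± 0.43 and Cd200 by 4.00 ± 0.42. The cell cycle lists rose in 22 of 22 G2/M genes (median 4.87) and 21 of 22 S phase genes (median 2.46), with Mki67 up by 4.87 ± 0.55. Nrgn, which encodes neurogranin, rose by 5.75 ± 0.93, E2f8 by 5.82 ± 0.68 and Kif4 by 5.66 ± 0.50. Anergy and receptor attenuation genes rose in 9 of 14 cases and fell in 1; Folr4 rose by 4.00 ± 0.25, Ikzf2 by 2.18 ± 0.28 and Egr2 by 1.89 ± 0.14. Activation surface markers rose in 7 of 18 cases and fell in 1, with Tnfrsf9, which encodes 4-1BB, up by 2.95 ± 0.27 and Icos by 1.67 ± 0.14. The chemokine genes Xcl1 (3.75 ± 0.33) and Ccl4 (2.53 ± 0.38) also rose. Glycolysis genes rose in 9 of 15 cases (Tpi1 by 1.65 ± 0.13), oxidative phosphorylation genes in 16 of 26 (Sdhb by 0.85 ± 0.11) and cholesterol genes in 9 of 18 with 1 lower (Cyp51 by 1.24 ± 0.12). Naive and memory genes fell in 12 of 18 cases and rose in 2, and interferon response genes fell in 7 of 19. The largest falls were in Igfbp4 (-4.91 ± 0.36), Fam211b (-4.16 ± 0.34), Plaur (-3.68 ± 0.41), Slc16a5 (-3.62 ± 0.70) and Itgae (-3.57 ± 0.31), and Il7r changed by -3.52 ± 0.21. Gzmb had a fold change of -0.07 ± 0.40 (adjusted p = 0.89).

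In TER119-SIINFEKL against Naive, 4657 genes were called, 2406 higher and 2251 lower (51.7% higher, but 45.4% with quantile normalization and 45.5% with the length and GC correction), and 1249 with a 2-fold requirement. The list test gave adjusted p = 2.7e-05 for inhibitory receptors, 3e-16 for G2/M, 3.7e-16 for S phase, 0.016 for anergy, 0.036 for activation markers, 0.00025 for glycolysis, 1.7e-05 for oxidative phosphorylation, 0.016 for cholesterol biosynthesis, 4e-06 for naive and memory genes and 0.028 for the interferon response. In that order they were adjusted p = 0.12, 0.19, 0.12, 0.36, 0.18, 0.12, 0.36, 0.36, 0.12 and 0.6 with an estimated correlation. When adjusted over the list alone, 10 anergy, 10 glycolysis and 20 oxidative phosphorylation genes were higher, and 14 naive and memory and 2 cholesterol genes were lower, with no change in the other counts of these lists. The activation list lost its call without TER119-SIINFEKL replicate 2 (adjusted p = 0.08), with quantile normalization (0.063), array weights (0.14) or the length and GC correction (0.051), and the interferon list without TER119-SIINFEKL replicate 2 (0.08) or replicate 3 (0.16). A pseudocount of 1 gave E2f8 3.38, Kif4 3.38, Fam211b -2.60 and Plaur -2.35.

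SIINFEKL was compared with Naive to see the response to free peptide, in 2 libraries that differed strongly. Inhibitory receptors rose in 6 of 10 cases and fell in 1. Lag3 rose by 5.90 ± 0.70 (SE, 2 against 3 libraries), standing at 7.18 and 3.31 log2 RPKM in replicates 1 and 2 against a Naive mean of -0.66 ± 0.35 (SD, n = 3). Ctla4 rose by 4.73 ± 0.48 and Pdcd1 by 4.54 ± 0.67, the latter at 4.91 and 1.22 log2 RPKM in the replicates. Anergy and receptor attenuation genes rose in 9 of 14 cases and fell in 1, with Folr4 up by 3.29 ± 0.28, Nrp1, which encodes neuropilin 1, by 3.86 ± 0.78, and Egr2 by 0.90 ± 0.16. G2/M genes rose in 16 of 22 cases by a median of 1.75, while of 22 S phase genes 2 were higher and 2 lower. Ccnb1 rose by 2.32 ± 0.36, and Cdt1, a replication licensing factor, changed by -1.16 ± 0.16. Mki67 stood at 4.40 and 1.53 log2 RPKM in the replicates against 0.82 ± 0.36 (SD, n = 3) in Naive cells. No glycolysis gene rose and 3 of 15 were lower, among them Eno1 (-0.56 ± 0.12); oxidative phosphorylation genes were lower in 1 of 26 cases. Nrn1, which encodes neuritin, rose by 5.48 ± 0.66. Il2ra, the alpha chain of the IL-2 receptor, was among the genes that fell (-4.24 ± 0.45), with -3.76 and -3.55 log2 RPKM in the replicates and 0.59 ± 0.57 (SD, n = 3) in Naive cells. The lowest value of SIINFEKL replicate 1 was -3.78, so the size of this fall and its rank depend on the unstated prior count; it was -3.16 with a pseudocount of 0.1 and -1.23 with 1. Igfbp4 (-3.83 ± 0.41), Ccr9 (-3.74 ± 0.49), Coro2a (-3.55 ± 0.24) and Tubb3 (-3.51 ± 0.39) fell too. Naive and memory genes were lower in 5 of 18 cases and higher in 2, and Il7r changed by -1.82 ± 0.23. Gzmb changed by -1.70 ± 0.45.

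In SIINFEKL against Naive, 1559 genes were called, 742 higher and 817 lower. By camera the lists had adjusted p = 7.3e-05 for inhibitory receptors, 0.00031 for anergy, 1e-10 for G2/M and 0.02 for naive and memory genes, and 0.36, 0.5, 0.74 and 0.74 as adjusted p with an estimated correlation. The S phase list did not pass (adjusted p = 0.82, median 0.11), nor did glycolysis (0.68, median -0.01) and oxidative phosphorylation (0.82, median -0.04). Counted as adjusted over the list alone, 8 inhibitory receptors, 22 G2/M and 3 S phase genes were higher, 9 naive and memory genes were lower, 0 oxidative phosphorylation genes passed, and the other counts of these lists did not change. The gene count was 363 without SIINFEKL replicate 1, 2438 without SIINFEKL replicate 2, 935 without Naive replicate 2, 932 without Naive replicate 3, 818 with array weights, 605 with only the 2 groups in the fit and 516 with a 2-fold requirement. Without SIINFEKL replicate 1 the fold changes were 2.69 for Pdcd1, 1.78 for Nrp1, 1.37 for Ccnb1, 0.55 for the G2/M median, -0.42 for Eno1 (call lost, also with quantile normalization), -1.01 for Gzmb (call lost, also without Naive replicate 1 or 3) and -0.30 for the S phase median, which then passed as lower (adjusted p = 0.0062). Without SIINFEKL replicate 2 the S phase median was 0.53 (adjusted p = 0.0045), the G2/M median 2.99 and Nrp1 5.94; the naive and memory list lost its call without replicate 1 (adjusted p = 0.22) and with quantile normalization (0.075). Tubb3 was at -1.40 and Pdcd1 at 2.90 with a pseudocount of 1.

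The 4 antigen groups shared part of their response. Against the same Naive libraries, 378 genes were higher and 332 lower in all 4 comparisons. In pairs, ERY1-OVA and TER119-SIINFEKL shared 1859 genes higher and 1556 lower, where 503.2 and 426.8 would be shared by independence, and their fold changes correlated across genes with r = 0.962. OVA and SIINFEKL shared 392 higher and 353 lower genes, where 181.2 and 189.1 would be shared by independence, with r = 0.491. Unchanged groups simulated against the same Naive libraries gave r from 0.446 to 0.502 with at most 0.02 genes shared, since the Naive libraries enter both sides. Their covariance was 0.0198 to 0.0199, against 0.2387 to 0.7259 measured, and genes are not independent replicates. The overlap of 710 genes was 208 without SIINFEKL replicate 1, 1195 without SIINFEKL replicate 2, 421 without Naive replicate 2 and 452 without Naive replicate 3.

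**Figure D2:**
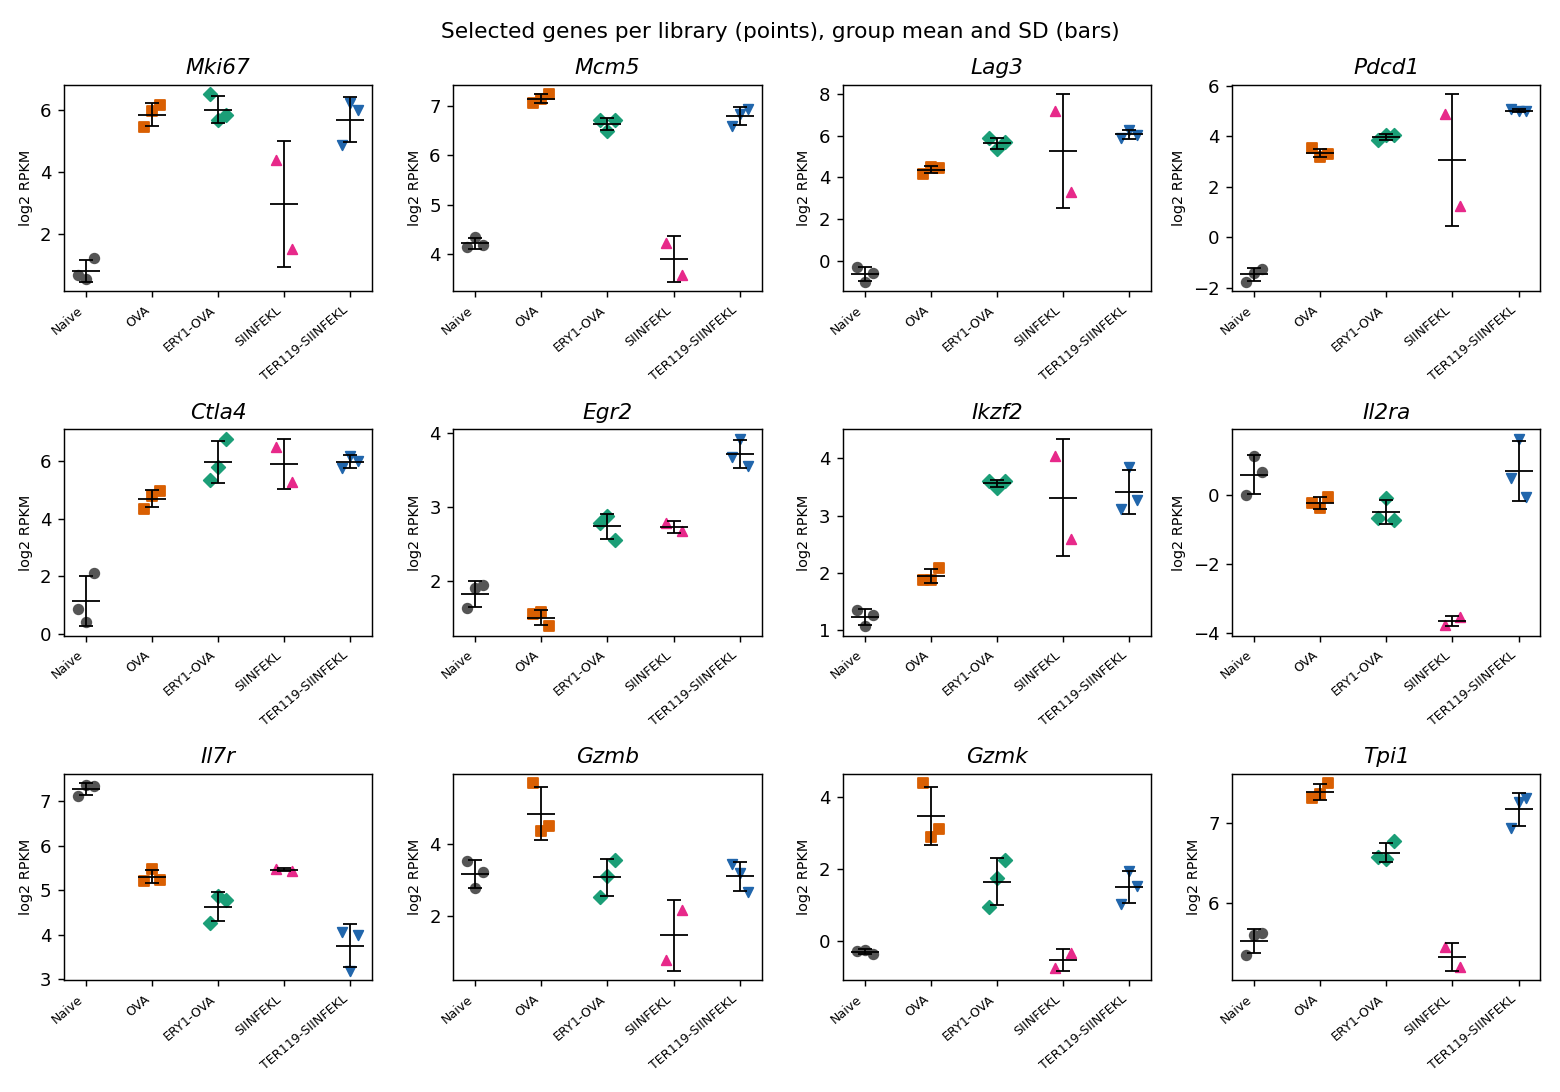
Points are log2 RPKM of 12 genes in each library by group, with the group mean and SD as bars (n = 3, and n = 2 for SIINFEKL). Lag3, Pdcd1 and Ctla4 lie above Naive in every antigen group, and Mcm5 lies near Naive in SIINFEKL and above it in the other antigen groups.

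**Figure D3:**
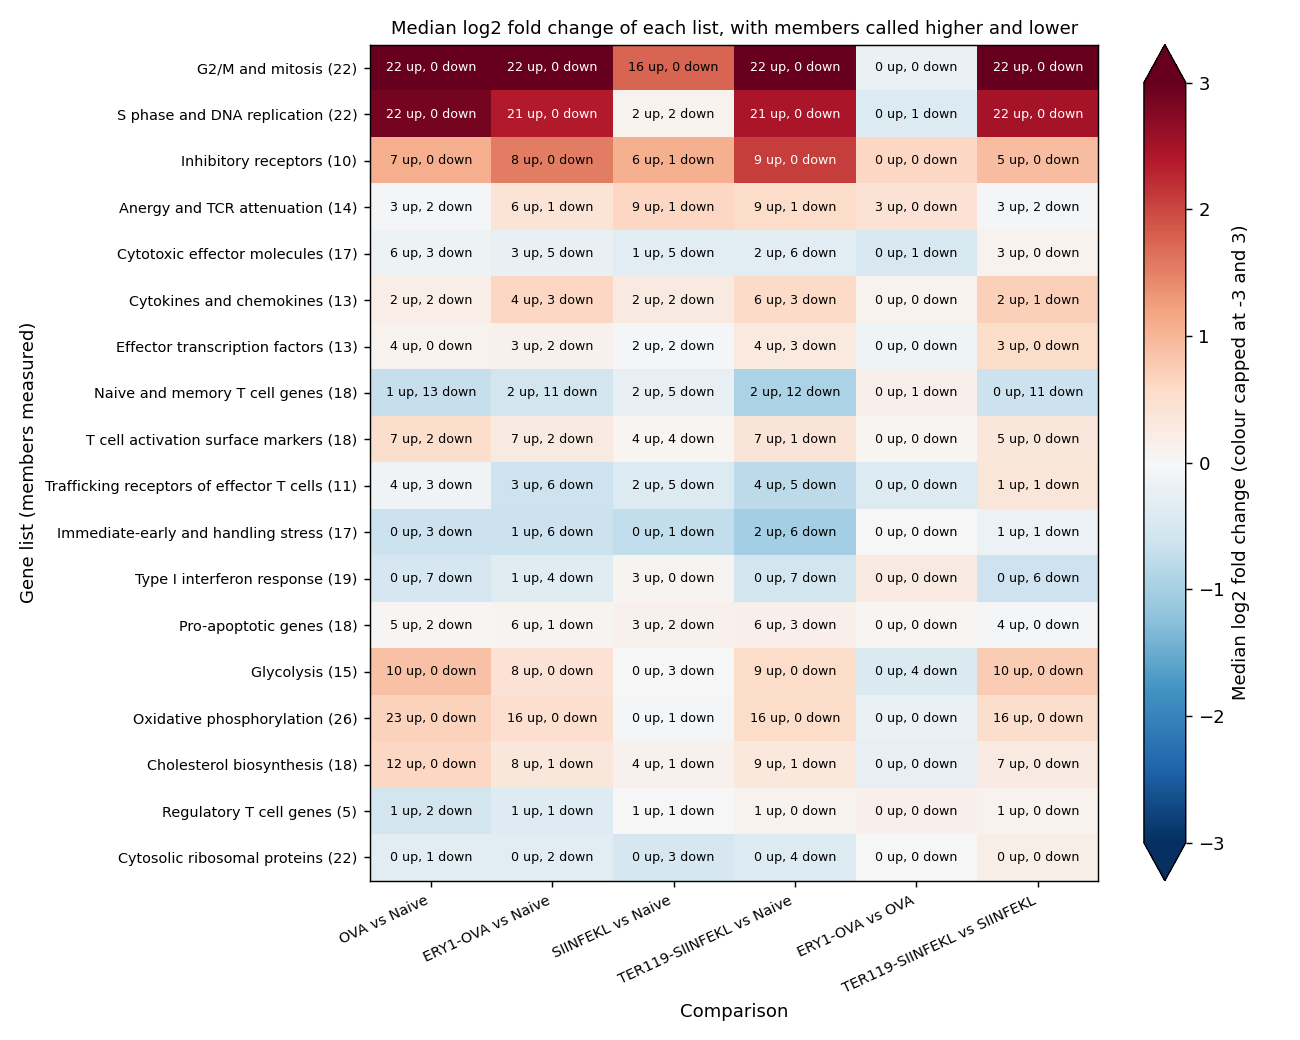
Colour gives the median log2 fold change of each of the 18 gene lists in 6 comparisons, and the text in each cell the number of members called higher and lower. The G2/M list is higher in all 22 members in OVA, ERY1-OVA and TER119-SIINFEKL against Naive, and in 16 in SIINFEKL against Naive.

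The series set ERY1-OVA against OVA to find what binding to erythrocytes changed for whole protein. Egr2 rose by 1.23 ± 0.14 (SE, 3 against 3 libraries, adjusted p = 0.0064), from a log2 RPKM of 1.51 ± 0.10 to 2.74 ± 0.17 (SD, n = 3 each), with 1.83 ± 0.18 (SD, n = 3) in Naive cells. The gene (ENSMUSG00000037868) lies on GRCm38 at chromosome 10, 67535475 to 67542188. Ikzf2 (ENSMUSG00000025997, chromosome 1, 69531214 to 69687245) rose by 1.62 ± 0.28 and Folr4 (ENSMUSG00000031933, chromosome 9, 14885814 to 14903949) by 1.43 ± 0.25. These were the 3 of 14 anergy and receptor attenuation genes that passed, all higher. Rasgef1a (1.76 ± 0.38) and Ephx1, an epoxide hydrolase gene (1.04 ± 0.16), completed the largest rises. Glycolysis genes moved the other way: 4 of 15 fell, namely Tpi1 (-0.76 ± 0.13), Eno1 (-0.61 ± 0.11), Aldoa (-0.56 ± 0.10) and Pgam1 (-0.45 ± 0.09). Gzmk (-1.81 ± 0.38), Tubb3 (-1.78 ± 0.35), Igfbp4 (-1.67 ± 0.36), the potassium channel gene Kcnk5 (-1.26 ± 0.25) and Chchd10 (-1.05 ± 0.21) had the largest falls. In the S phase list 1 of 22 genes fell, Ccne1, which encodes cyclin E1 (-0.75 ± 0.16), and in the G2/M list none passed, with Mki67 at 0.16 ± 0.55 (adjusted p = 0.93). Gzmb, with a fold change of -1.76 ± 0.40, missed the threshold (adjusted p = 0.051). No inhibitory receptor passed, with Lag3 at 1.26 ± 0.63 (adjusted p = 0.33), Ctla4 at 1.27 ± 0.43 (0.15) and Pdcd1 at 0.64 ± 0.59 (0.65). These SEs include the spread of the SIINFEKL pair, which is outside the comparison. For Lag3 the SD was 0.18 in OVA and 0.26 in ERY1-OVA but 2.73 in SIINFEKL. For Pdcd1 it was 0.17, 0.12 and 2.61 in that order. Lag3 and Pdcd1 did not overlap between OVA and ERY1-OVA, and both passed with the SIINFEKL group left out of the fit. Without ERY1-OVA replicate 1 every one of these gene calls was lost (Egr2 at adjusted p = 0.064, Folr4 at 0.082), and every one but that of Egr2 was also lost without any single OVA library and without ERY1-OVA replicate 2. Pecam1 was higher (0.72 ± 0.14), a call lost when any 1 library of these groups or TER119-SIINFEKL replicate 3 was left out (0.62 to 0.80). Tbx21 (-0.63 ± 0.22, adjusted p = 0.16) and Il7r (-0.67 ± 0.21, 0.12) did not pass either.

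In ERY1-OVA against OVA, limma called 104 genes, 40 higher and 64 lower (38.5% higher, but 60.6% with quantile normalization and 52.1% with no trend). Camera gave adjusted p = 2.7e-08 for glycolysis and 0.048 with an estimated correlation, the single list call of the 10 comparisons to pass in that way, and it did not once a replicate block was added (adjusted p = 0.063). With the preset correlation camera called 3 lists higher and 5 lower, not all of them named here. The anergy list was higher (adjusted p = 1.8e-06, and adjusted p = 0.18 with an estimated correlation), as was the inhibitory receptor list (0.0042, and adjusted p = 0.32 with an estimated correlation), and the S phase list was lower (9.9e-07, and adjusted p = 0.32 with an estimated correlation). Adjusted over the list alone, 10 glycolysis and 9 S phase genes were lower, 6 anergy genes and 4 inhibitory receptors were higher with 1 member of each lower, and 0 G2/M genes passed by limma. The gene count rested on single libraries: without ERY1-OVA replicate 1, 2 or 3 it was 0 (1558 at an unadjusted p under 0.05), 3 and 15, without OVA replicate 1, 2 or 3 it was 1, 1 and 2, without TER119-SIINFEKL replicate 1, 2 or 3 it was 168, 69 and 4, without Naive replicate 1 or 3 it was 56 each, and without SIINFEKL replicate 1 or 2 it was 359 and 360. It was 359 with the SIINFEKL group left out of the fit, where Lag3 (1.26, adjusted p = 0.0061), Pdcd1 (0.03) and Gzmb (0.017) passed, 13 without OVA replicate 1 and TER119-SIINFEKL replicate 1, 66 with quantile normalization, 236 with the length and GC correction, 2468 with array weights and 11 with a 2-fold requirement. By a pseudocount of 1 the changes were Rasgef1a 0.89, Tubb3 -0.78 and Kcnk5 -0.82, and Gzmb passed (adjusted p = 0.037).

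TER119-SIINFEKL was set against SIINFEKL to find what binding to erythrocytes changed for the peptide. Replication and division genes were far higher after targeted peptide. All 22 S phase genes rose, by a median of 2.50, and all 22 G2/M genes were higher, by a median of 3.02; Mcm5 rose by 2.90 ± 0.17 (SE, 3 against 2 libraries), from a log2 RPKM of 3.90 ± 0.47 (SD, n = 2) to 6.80 ± 0.18 (SD, n = 3), with 4.21 ± 0.11 (SD, n = 3) in Naive cells. Mcm7 rose by 2.44 ± 0.15, Kif20a by 3.17 ± 0.41 and Ccnb1 by 2.74 ± 0.36. Among the largest rises were those of Orc1, a subunit of the origin recognition complex (4.50 ± 0.40), Il2ra (4.34 ± 0.45), Fignl1 (4.01 ± 0.61) and Mcm10 (3.95 ± 0.54). Glycolysis genes rose in 10 of 15 cases, among them Tpi1 (1.85 ± 0.14) and Gapdh (1.13 ± 0.12), and oxidative phosphorylation genes in 16 of 26. The chemokine genes Xcl1 (3.19 ± 0.37) and Ccl4 (3.05 ± 0.42) rose, as did Egr2 (0.99 ± 0.16) and Gzmb (1.63 ± 0.45). Naive and memory genes fell in 11 of 18 cases, with Il7r at -1.70 ± 0.23, S1pr1 at -1.32 ± 0.12 and Klf2, a factor of resting T cells, at -0.93 ± 0.16. Interferon response genes were lower in 6 of 19 cases, including Stat2, a signalling factor of that response (-0.87 ± 0.15). The largest falls were in the GABA receptor gene Gabbr1 (-2.14 ± 0.35), Rgmb (-2.08 ± 0.24), Rapgef4 (-1.87 ± 0.15), Wfikkn2 (-1.86 ± 0.30) and Tbx6 (-1.85 ± 0.41). Inhibitory receptors were higher in 5 of 10 cases, including Lair1 (1.40 ± 0.28), Tigit (1.69 ± 0.41) and Pdcd1 (1.97 ± 0.67), while Lag3 had a fold change of 0.82 ± 0.70 (adjusted p = 0.38) and Ctla4 of 0.09 ± 0.48 (0.9). Of the cell type markers, Cd22 (B cells, 1.61 ± 0.16) and Klrb1c (NK cells, 1.21 ± 0.36) were higher. Pecam1 (-0.58 ± 0.15) and Cd8b1 (-0.62 ± 0.12, and -0.97 with the length and GC correction) were lower. Klrb1c was at 0.75 without TER119-SIINFEKL replicate 1 and lost its call without SIINFEKL replicate 2 (1.04), and Pecam1 lost its call without SIINFEKL replicate 1 (-0.36).

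In TER119-SIINFEKL against SIINFEKL, 3664 genes were called, 1996 higher and 1668 lower (54.5% higher, but 46.3% with quantile normalization and 46.6% with the length and GC correction), 2131 with only the 2 groups in the fit and 941 with a 2-fold requirement. The list test gave adjusted p = 1.1e-18 for S phase, 4.5e-12 for G2/M, 1e-05 for glycolysis, 3.6e-06 for oxidative phosphorylation, 8.6e-06 for naive and memory genes, and 0.00057 for the interferon response. In that order they were adjusted p = 0.1, 0.32, 0.1, 0.37, 0.13 and 0.43 with an estimated correlation. With the preset correlation camera called 5 lists higher and 2 lower, not all of them named here. The inhibitory receptor list did not pass (median 0.92, adjusted p = 0.057). With p-values adjusted over the list alone, 17 oxidative phosphorylation genes were higher and 13 naive and memory and 10 interferon genes lower, with no change in the other counts of these lists. Without SIINFEKL replicate 2, which lay near the Naive libraries, the G2/M median was 1.81, Fignl1 2.4, Mcm10 2.53, Ccnb1 1.8 and Pdcd1 0.12, and Pdcd1 lost its call, as it did without any single TER119-SIINFEKL library and without OVA replicate 1 and TER119-SIINFEKL replicate 1 together. Lag3 was at -1.11 without SIINFEKL replicate 2; without replicate 1, Pdcd1 was at 3.81, Lag3 at 2.75 (adjusted p = 4.6e-06), the inhibitory receptor list at adjusted p = 0.00014 (also under the threshold without Naive replicate 3, 0.036, or TER119-SIINFEKL replicate 3, 0.048), and Gzmb at 0.94 with its call lost. Il2ra lies near the lowest values in SIINFEKL cells, and its rise was 3.26 with a pseudocount of 0.1 and 1.31 with 1, which also gave Orc1 2.31, Mcm10 2.57, Rgmb -1.21, Wfikkn2 -1.19 and Tbx6 -1.21.

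The effect of targeting differed between protein and peptide. Protein was targeted with ERY1 and peptide with a TER119 fragment, so antigen form and targeting agent cannot be told apart. Between the soluble groups 4135 genes were called, with a mean absolute log2 fold change of 0.538. Between the targeted groups these were 55 and 0.175, so the difference lay mostly between the soluble groups. Across 9793 genes, the fold changes of ERY1-OVA against OVA and of TER119-SIINFEKL against SIINFEKL, which share no library, ran in opposite directions (Pearson r = -0.449, Spearman rho = -0.562, genes not being independent replicates). Deviations within groups ran together in OVA and TER119-SIINFEKL libraries of the same number (r = 0.67, 0.29 and 0.25). Since deviations within a group sum to 0, these r values are not separate evidence. A shift shared by those groups would by itself make the correlation of targeting effects negative. That correlation was -0.422 without replicate 1 of both groups, and -0.44 with a replicate block. Of the genes lower with targeting of the protein, 62 were higher with targeting of the peptide, where 13 would be by independence, and 0 were lower in both, where 10.9 would be. Only 2 genes were higher in both, where 8.2 would be, and 16 were higher with the protein and lower with the peptide. The test of the difference itself called 3694 genes, 1676 with the more positive change for the protein and 2018 with the more positive change for the peptide (45.4% the former, but 52.5% with quantile normalization and 52% with the length and GC correction). S phase genes differed in 22 of 22 cases and glycolysis genes in 11 of 15, all with the more positive change for the peptide (adjusted p = 4.9e-17 and 1e-06, and adjusted p = 0.13 and 0.11 with an estimated correlation). The counts adjusted over the list alone were the same. Egr2 was higher with targeting in both forms, and its difference between forms was 0.24 ± 0.21 (adjusted p = 0.4). The correlation was -0.281 without SIINFEKL replicate 1 and -0.584 without SIINFEKL replicate 2, and 1740 genes differed with a 2-fold requirement.

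**Figure D4:**
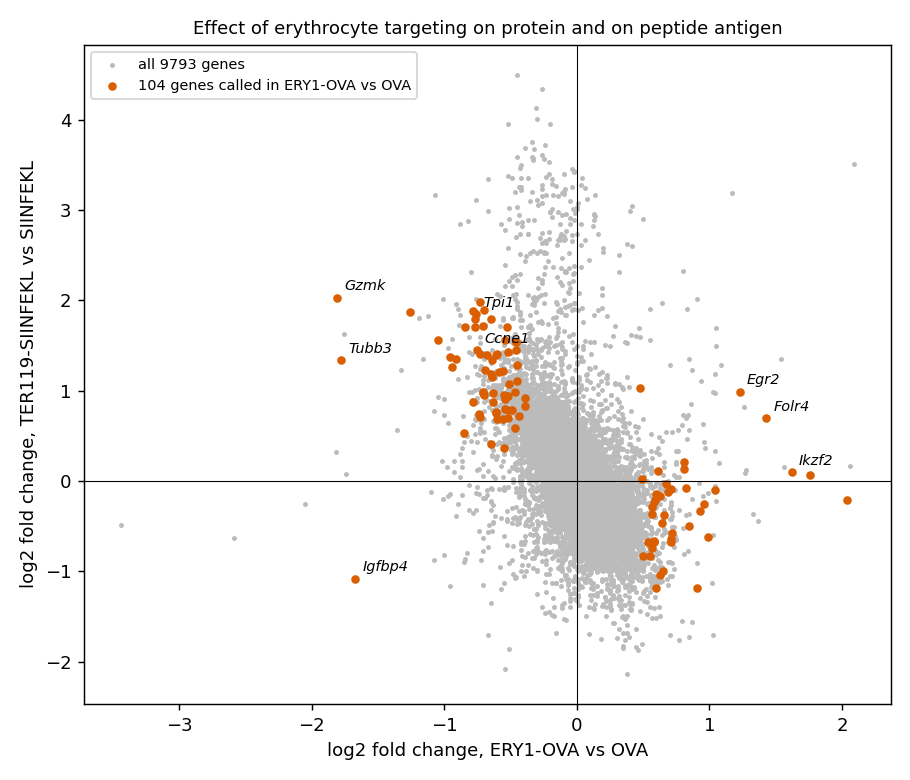
Each point is a gene, with its log2 fold change for ERY1-OVA against OVA on the horizontal axis and for TER119-SIINFEKL against SIINFEKL on the vertical axis; orange points are the 104 genes called in the first. Egr2 and Folr4 lie in the upper right, and Gzmk, Tpi1 and Tubb3 in the upper left.

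Averaged over protein and peptide, targeted antigen was compared with soluble antigen. Egr2 was higher by 1.11 ± 0.11 (SE, 6 against 5 libraries), the chemokine gene Xcl1 by 2.18 ± 0.25, the activation marker gene Cd83 by 1.56 ± 0.21, Trpm1 by 1.46 ± 0.16 and the immediate-early gene Nr4a3 by 1.37 ± 0.14. Il7r (-1.19 ± 0.16), Rgmb (-1.31 ± 0.16), Wfikkn2 (-1.18 ± 0.20) and Klf2 (-0.67 ± 0.11) were lower, Rgmb at -0.75 and Wfikkn2 at -0.73 with a pseudocount of 1. Among cell type markers, Cd22 was higher (0.73 ± 0.10) and Cd8b1 lower (-0.36 ± 0.08, a call lost without OVA replicate 2, -0.34, or SIINFEKL replicate 2, -0.35). S phase genes were higher in 20 of 22 cases and G2/M genes in 21 of 22, as were 3 of 10 inhibitory receptors, and 5 of 14 anergy genes were higher with 1 lower. The cell cycle part lay in the peptide: S phase and G2/M medians were 2.50 and 3.02 (1.81 for G2/M without SIINFEKL replicate 2) for TER119-SIINFEKL against SIINFEKL, but -0.42 and -0.20 for ERY1-OVA against OVA. Limma called 778 genes, 552 higher and 226 lower. Camera called 7 lists higher and 2 lower, not all of them named here. For those named it gave adjusted p = 8.2e-24 for S phase, 4.1e-16 for G2/M, 0.00013 for inhibitory receptors and 0.013 for anergy, and 0.062, 0.2, 0.17 and 0.36 as adjusted p with an estimated correlation. When adjusted over the list alone, 22, 22, 4 and 6 members were higher and 1 anergy gene lower. The count was 390 without OVA replicate 2, 474 without ERY1-OVA replicate 2, 447 without TER119-SIINFEKL replicate 3 and 178 with a 2-fold requirement. Without SIINFEKL replicate 2 the medians were 0.78 for G2/M, 0.32 for inhibitory receptors and 0.04 for anergy, whose call was then lost (adjusted p = 0.19), as it was without OVA replicate 1 (0.16, adjusted p = 0.081).

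The erythrocyte-targeted antigens were also set against each other. Relative to TER119-SIINFEKL, ERY1-OVA cells had less Ccl4 (-1.92 ± 0.38, SE, 3 against 3 libraries), Xcl1 (-1.75 ± 0.33), Tnfsf14, which encodes LIGHT (-1.45 ± 0.18), Tnfrsf9 (-1.39 ± 0.27), Car12 (-1.37 ± 0.22) and Egr2 (-0.98 ± 0.14). The B cell gene Cd22 was lower as well (-0.91 ± 0.14), a call lost without any 1 ERY1-OVA library or TER119-SIINFEKL replicate 2 or 3 (-0.94 to -0.84). They had more Rapgef4 (0.94 ± 0.14), Ggt1 (0.92 ± 0.18), S1pr1 (0.60 ± 0.11) and the IL-6 receptor genes Il6ra (0.67 ± 0.12) and Il6st (0.49 ± 0.10). In the naive and memory list 1 of 18 genes was higher, S1pr1, and in the glycolysis list 1 of 15 was lower, the hexokinase gene Hk2 (-1.22 ± 0.25). Limma called 55 genes, 7 higher and 48 lower, and 16 with a 2-fold requirement. Camera called 2 lists higher and 5 lower, not all of them named here. It gave adjusted p = 1.1e-08 for naive and memory genes and 3.9e-06 for glycolysis, each with adjusted p = 0.05 with an estimated correlation, just over the threshold. Counted as adjusted over the list alone, 7 naive and memory genes were higher and 5 glycolysis genes lower. The count was 13, 0 (799 at an unadjusted p under 0.05 by limma) and 18 without ERY1-OVA replicates 1, 2 and 3, and 0 without TER119-SIINFEKL replicate 2 (985) or 3 (801). It was 22, 25 and 29 without Naive replicates 1, 2 and 3, 25 and 19 without OVA replicates 2 and 3, 163 and 162 without SIINFEKL replicates 1 and 2, 163 without that group, 29 with no trend, 97 with the length and GC correction and 2477 with array weights.

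Last, soluble protein was compared with soluble peptide. OVA cells had more transcript of all 22 S phase genes (median 2.93) and all 22 G2/M genes (median 3.42), and Orc1 (4.92 ± 0.40, SE, 3 against 2 libraries) was among the largest rises, with Mcm10 (4.44 ± 0.54), Fignl1 (4.30 ± 0.61) and Clspn (4.16 ± 0.62). Gzmk (3.98 ± 0.43), Gzmb (3.36 ± 0.45) and Tbx21 (1.11 ± 0.25) were higher too. Markers fixed for other cells moved in the same comparison. Itgax of dendritic cells (1.49 ± 0.36, a call lost without SIINFEKL replicate 1, 1.16), Cd22 (0.86 ± 0.16) and the erythroid gene Car2 (0.96 ± 0.34) were higher and Pecam1 (-1.24 ± 0.15) lower. The call of Car2 was lost without OVA replicate 1 or 2 or SIINFEKL replicate 2 (0.61 to 0.96), with quantile normalization (0.83) and with the length and GC correction (0.68). Of the identity genes, Cd3e was lower (-0.39 ± 0.10, and -0.69 with quantile normalization), as was Cd8a (-0.31 ± 0.11, and -0.62), whose call was lost without any 1 OVA library, Naive replicate 3, ERY1-OVA replicate 2 or 3, SIINFEKL replicate 1 or TER119-SIINFEKL replicate 3 (-0.32 to -0.23). Anergy and receptor attenuation genes were lower in 10 of 14 cases and higher in 1, with Egr2 at -1.22 ± 0.16. Interferon response genes were lower in 9 of 19 cases. Among the largest falls were those of Nrn1 (-2.56 ± 0.66), the signalling inhibitor gene Spry1 (-2.25 ± 0.47), Adamts6 (-2.12 ± 0.35) and Rasgef1a (-1.97 ± 0.42). Limma called 4135 genes, 2189 higher and 1946 lower (52.9% higher, but 44.1% with quantile normalization and 43.6% with the length and GC correction), and 1097 with a 2-fold requirement. Camera called 5 lists higher and 3 lower, not all of them named here. The list test gave adjusted p = 5.8e-19, 3.5e-12, 0.0014 and 0.001 for S phase, G2/M, anergy and interferon, and 0.097, 0.3, 0.3 and 0.42 as adjusted p with an estimated correlation. Adjusted over the list alone, 13 interferon genes were lower and the other counts did not change. Without SIINFEKL replicate 2 the G2/M median was 2.20, Fignl1 2.68, Clspn 2.61 and Nrn1 -4.13; without SIINFEKL replicate 1 Spry1 was at -1.42, and Nrn1 at -0.99 with its call lost. Orc1 was at 2.68 and Rasgef1a at -1.03 with a pseudocount of 1.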

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

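Tests of other splits of the libraries were planned; the tests of the 3 patterns weighed here were chosen only after the result was seen.

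The effect of targeting differed between protein and peptide by a test of the difference in 3694 genes, 37.7% of those tested. It also differed in 39 of the 48 named genes examined. Antigen form was tied to the targeting agent, ERY1 for protein and a TER119 fragment for peptide, so their parts cannot be told apart. Named genes were in part chosen by their calls in these same libraries, so their share is no separate support for the difference. Differences are log2 values, the effect for protein minus that for peptide. They were positive for Gabbr1 (2.52), Rapgef4 (2.33), Tbx6 (2.20), Mx1 (2.06), Rasgef1a (1.69), Rgmb (1.54), Ikzf2 (1.52), Stat2 (1.48), S1pr1 (1.44), Wfikkn2 (1.35), Pecam1 (1.29), Ephx1 (1.14), Il7r (1.03) and Cd8b1 (0.53). Negative differences under 3 in size were those of Tbx21 (-0.97), Aldoa (-1.25), Eno1 (-1.37), Gapdh (-1.55), Pgam1 (-1.57), Cd22 (-1.76), Xcl1 (-2.02), Lair1 (-2.12), Ccne1 (-2.21), Mki67 (-2.57), Chchd10 (-2.61), Tpi1 (-2.61), Ccl4 (-2.63) and Mcm7 (-2.83). Larger ones were those of Ccnb1 (-3.11), Tubb3 (-3.11), Kcnk5 (-3.14), Gzmb (-3.39), Kif20a (-3.40), Mcm5 (-3.41), Gzmk (-3.84), Fignl1 (-4.31), Mcm10 (-4.47), Il2ra (-4.60) and Orc1 (-4.95). Among the lists, median differences were -3.19 for G2/M, -2.86 for S phase, 0.71 for naive and memory genes, 1.00 for the interferon response, -1.37 for glycolysis, -0.73 for oxidative phosphorylation and -0.34 for cholesterol biosynthesis. In that order the list test gave adjusted p = 2.4e-09, 4.9e-17, 4.7e-05, 0.00063, 1e-06, 4.2e-06 and 0.0072, and adjusted p = 0.35, 0.13, 0.25, 0.47, 0.11, 0.35 and 0.34 with an estimated correlation, by which none passed. The peptide side of each difference rests on the 2 SIINFEKL libraries. Without SIINFEKL replicate 2 the difference was -1.13 for Mki67, -0.62 for Tbx21 and 0.51 for Cd8b1, each with the call lost, -2.70 for Fignl1 and -2.02 for G2/M. Without SIINFEKL replicate 1 it was -4.00 for Mki67, and calls were lost for Ikzf2 (0.80), Rasgef1a (1.38), Il7r (1.00) and Wfikkn2 (1.27). Other single libraries ended 5 calls. They were those of Cd8b1 (0.48) without OVA replicate 3, Rasgef1a (1.5 to 1.68) without replicate 1 or 2 of OVA or TER119-SIINFEKL, or 1 or 3 of ERY1-OVA, Mki67 (-2.49 to -2.30) without OVA replicate 3 or replicate 2 or 3 of ERY1-OVA or TER119-SIINFEKL, Tbx21 (-0.89 to -0.74) without OVA replicate 1, ERY1-OVA replicate 3 or TER119-SIINFEKL replicate 2, and Mx1 (1.8 and 1.81) without OVA replicate 2 or TER119-SIINFEKL replicate 3. The difference for Cd8b1 was 0.93 with quantile normalization and 0.95 with the length and GC correction, settings in which the call of Tbx21 was lost (-0.89 and -0.82) and oxidative phosphorylation was at -0.48 and -0.44. Array weights ended the calls of Rasgef1a (1.11) and Tbx21 (-0.71). Without replicate 1 of both OVA and TER119-SIINFEKL those calls (1.53 and -0.85) and that of Wfikkn2 (1.23) were lost, with oxidative phosphorylation at -0.47. A pseudocount of 1 ended none, but moved 7 differences by over 1.5 times, to -1.42 for Il2ra, whose SIINFEKL values lie near the lowest of their libraries, -2.70 for Orc1, -1.69 for Kcnk5, -1.10 for Tubb3, 1.39 for Tbx6, 0.91 for Rgmb and 0.85 for Rasgef1a.

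SIINFEKL replicate 2 lay near the Naive libraries, with r of 0.971 to 0.974 to them and 0.960 to SIINFEKL replicate 1. A Naive library under a SIINFEKL label is argued against, since at least 287 genes were called with this library alone against any 2 Naive libraries (363 against all 3), where a single Naive library against the other 2 gave at most 2. A mixture of Naive RNA with RNA like that of replicate 1 needs 1 share for all genes, but the median share was 13.6% from 51 raised genes (quartiles 5.7 to 20) and 68.9% from 58 lowered genes (58.4 to 83.4). A weaker or later response of the cells in that mouse may account for the position, and this was not tested.

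OVA replicate 1 and TER119-SIINFEKL replicate 1 deviated together from their groups, with a correlation of 0.67 across genes. Gene length and GC content as the whole cause are argued against, since the correlation was 0.53 after they were corrected. Genes of MHC class II were high in both, with a median deviation of at least 1.26 against at most 0.3 in any other library, but they were singled out for this, so the value does not test whether RNA of cells that express them was present. That explanation stays open, as does what moved the remaining genes. The cells were sorted for CD3e, CD8 and CD45.1, but how far this removed cells that express MHC class II is not known.

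Cd22, a B cell gene, was higher than Naive by 4.18, 3.33, 4.03 and 4.94 (log2) in OVA, SIINFEKL, ERY1-OVA and TER119-SIINFEKL. B cell RNA is argued against by Cd79b, Cd74, H2-Aa, H2-Ab1 and H2-Eb1, which B cells express. Their highest median change over these comparisons was 0.28. Only Cd79b among them was fixed as a B cell marker, and the others were fixed as dendritic cell and MHC class II markers. Cd79b changed by 0.22, 0.47, 0.6 and 0.6 in the order given, with no call but each above 0. Of 9 fixed B cell markers, 3 had values. Expression by the T cells and reads from related genes may each account for it, and neither was tested.

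For comparisons of 3 against 3 libraries, the 10 possible splits are too few for a share under 0.05; in each, 1 split, the real one, reached the real count. Counts by limma for the real split and the highest other were 4659 and 0 for OVA against Naive, 3905 and 0 for ERY1-OVA, 4657 and 0 for TER119-SIINFEKL, 104 and 0 for ERY1-OVA against OVA, and 55 and 0 for ERY1-OVA against TER119-SIINFEKL. At an unadjusted p under 0.05 the highest other splits gave 552, 858, 770, 1815 and 2098 genes, and the real ones 5370, 4798, 5391, 1683 and 1065. For targeted against soluble antigen, 10 of 100 splits within antigen form gave at least 778 genes, the highest other 2672. Each of the 9 others kept both SIINFEKL libraries against all 3 of TER119-SIINFEKL, and so the peptide contrast, while mixing OVA with ERY1-OVA. That points to a structure of the samples. By the rule set beforehand, chance was to stay an explanation if at least 0.05 of the splits reached the real count, as they did here. The rule made no allowance for splits that keep the peptide contrast, so chance is not excluded by this count. The 89 splits that broke the peptide contrast gave at most 2 genes each. Where groups differ, a split that mixes them adds their difference to the spread within groups, which by itself lowers the count. Low counts in the other splits, here and for the comparisons above, are thus no support for the real ones.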

How the results depend on the processing

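The pseudocount of 1, the length and GC correction, both sets of left-out libraries other than single ones, and the replicate block for the correlation of targeting effects or with an estimated correlation were tests added after the data were seen. Depth is unknown, so its limit could not be computed. Robust moderation was not run for the lists, since camera has no such option. The cause was not tested for any change given here, except that a 2-fold requirement adds a condition and leaving out libraries lowers their number. Median-of-ratios rescaling, no filter and a pseudocount of 0.1 reversed no list and no named gene; leaving out single libraries reversed 2 lists and 4 fold changes of 3 named genes.

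With a 2-fold requirement the counts were 1083 (OVA against Naive), 516 (SIINFEKL), 1009 (ERY1-OVA), 1249 (TER119-SIINFEKL), 11 (ERY1-OVA against OVA), 941 (TER119-SIINFEKL against SIINFEKL), 16 (between targeted groups), 1097 (between soluble groups), 178 (targeted against soluble) and 1740 (difference between forms). SIINFEKL against Naive gave 818 with array weights, 605 with only its groups fitted and 363 to 2438 without single libraries, and TER119-SIINFEKL against SIINFEKL gave 2131 with only its groups fitted. ERY1-OVA against OVA gave 66 with quantile normalization, of which 60.6% were higher against 38.5% as deposited, 2468 with array weights, 236 with the length and GC correction, 13 without OVA replicate 1 and TER119-SIINFEKL replicate 1, 359 without the SIINFEKL group and 0 (1558 at an unadjusted p under 0.05 by limma) to 360 without single libraries. ERY1-OVA against TER119-SIINFEKL gave 29 without trend, 2477 with array weights, 97 with the length and GC correction, 163 without the SIINFEKL group and 0 (799 at an unadjusted p under 0.05 by limma) to 163 without single libraries. Targeted against soluble gave 390 to 1092 without single libraries. The array weights ranged from 0.28 to 22.74 and their estimation stopped before it converged.

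Of 80 list calls, 1 held with an estimated correlation, and fry made 86. Without single libraries the correlation of targeting effects was -0.584 to -0.281 and the overlap of calls against Naive 208 to 1195. Reversed medians or fold changes ranged, without single libraries, from -0.30 to 0.53 for S phase in SIINFEKL against Naive, -0.07 to 0.43 for interferon in ERY1-OVA against TER119-SIINFEKL, -1.08 to 0.96 for Eomes in SIINFEKL against Naive, -1.11 to 2.75 for Lag3 in TER119-SIINFEKL against SIINFEKL, and -1.56 to 2.13 for Pdcd1 and -2.81 to 1.05 for Lag3 in OVA against SIINFEKL.

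The labels name no link between libraries of the same replicate number. Of 26 such pairs, 14 had a residual correlation above 0.1 (mean 0.065), and 6 of 14 libraries correlated best with their own number. Of the 15 pairs without an ERY1-OVA library, 12 exceeded 0.1 (mean 0.206), among them all 3 of OVA with TER119-SIINFEKL and all 3 of Naive with TER119-SIINFEKL, and pairs with one had a mean of -0.127. Deviations within a group sum to 0, so pairs from the same groups are not separate evidence, and no chance level was computed. These values thus neither show nor exclude a link between some groups. With the replicate block ERY1-OVA against OVA gave 69 genes and ERY1-OVA against TER119-SIINFEKL 32, and the correlation of targeting effects was -0.44. Among the named genes the block ended 21 calls and brought 5, with Ifng against Naive among the latter after OVA (adjusted p = 0.012) and TER119-SIINFEKL (0.026). In ERY1-OVA against OVA it ended those of Rasgef1a, Gzmk, Tubb3, Igfbp4, Kcnk5, Ccne1 and Pgam1 (adjusted p = 0.052 to 0.067), and in ERY1-OVA against TER119-SIINFEKL those of Ccl4, Il6st and Hk2 (0.066 to 0.092). The block changed the call of 2 lists, both immediate-early, now lower than Naive after OVA (adjusted p = 0.034) and TER119-SIINFEKL (0.032). These were adjusted p = 0.54 and 0.48 with an estimated correlation, by which the blocked fit called 0 lists.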

Other observations

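Genes of cell death and movement shifted within lists that did not pass by camera, which gave the adjusted p-values below. Fry called 10, 11 and 13 lists against Naive after OVA, ERY1-OVA and TER119-SIINFEKL. Camera called 6, 7 and 8 higher and 3, 2 and 3 lower, so not passing holds for camera alone. Against Naive, the p53 target Bbc3 fell by 1.94 ± 0.35 after ERY1-OVA and by 2.46 ± 0.35 after TER119-SIINFEKL (log2, SE, 3 against 3 libraries). Soluble antigen groups lay below Naive too. Bbc3 stood at 2.75 to 3.12 log2 RPKM after OVA and at 1.89 and 3.6 in the SIINFEKL replicates, against 4.21 to 4.79 in Naive libraries. Of 18 pro-apoptotic genes, 5, 6 and 6 were higher and 2, 1 and 3 lower after OVA, ERY1-OVA and TER119-SIINFEKL (adjusted p = 0.54, 0.38 and 0.28). Integrin beta 1 (Itgb1) was higher in these 3 comparisons, and the chemokine receptor Cxcr3 after OVA and ERY1-OVA, in the latter by 0.86 and by 0.53 without Naive replicate 1. After TER119-SIINFEKL, 4 of 11 trafficking receptors were higher and 5 lower (adjusted p = 0.46). Irf4, Irf8 and Batf were higher in the same comparisons, where 4, 3 and 4 of 13 effector transcription factors were higher and 0, 2 and 3 lower (adjusted p = 0.23, 0.38 and 0.28).

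After TER119-SIINFEKL, the orphan nuclear receptor gene Nr4a3 was higher than Naive by 1.93 ± 0.19 (SE, 3 against 3 libraries). The immediate-early list had 2 genes higher and 6 lower of 17 (adjusted p = 0.14, and 0.032 with a replicate block, where adjusted p = 0.48 with an estimated correlation). Its score was lowest in replicate 1 in each of the 5 groups, and below that of the Naive library of the same number in 11 of 11 libraries from antigen groups (TER119-SIINFEKL -0.48, -1.12 and -0.64), a pattern seen after the fact. Among 5 measured regulatory T cell genes 1 was higher, Ctla4 (adjusted p = 0.61 for the list). Cytokine and chemokine genes were higher in 6 and lower in 3 of 13 cases (adjusted p = 0.14). Counts adjusted over the list alone were 6 lower for trafficking receptors and 8 lower for immediate-early genes, and did not differ for the other counts given here.

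Cytosolic ribosomal protein genes were lower than Naive in 1, 3, 2 and 4 of 22 cases after OVA, SIINFEKL, ERY1-OVA and TER119-SIINFEKL, with medians of -0.33, -0.50, -0.34 and -0.42. In that order the list had adjusted p = 0.044, 0.00015, 0.033 and 0.016, and adjusted p = 0.82, 0.81, 0.69 and 0.63 with an estimated correlation. Adjusted over the list alone, 0, 3, 0 and 0 genes were lower. With quantile normalization the list passed in none of the 4 (adjusted p = 0.71, 0.26, 0.38 and 0.28). After SIINFEKL it passed whichever library was left out. It was lost after OVA without Naive replicate 1 or 3, OVA replicate 2 or 3, ERY1-OVA replicate 3 or either SIINFEKL library (medians -0.33 to -0.24), after ERY1-OVA without Naive replicate 1 or 3 or ERY1-OVA replicate 1 (-0.33 to -0.24), and after TER119-SIINFEKL without its replicate 2 (-0.22) or 3 (-0.37).

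The CD4 lineage gene Zbtb7b, singled out after its values were seen, stood at 9.93 RPKM in SIINFEKL replicate 1 and at 0.76 to 1.48 RPKM elsewhere.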
